A study of Mus musculus with 30 samples.

How the data were processed

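Liver RNA of 30 mice, 1 mouse per array, was labelled with Cy3 and hybridized to one-colour Agilent arrays. The deposited values are array intensities on a linear scale, read with Agilent Feature Extraction per the submitters' processing notes, with neither its version nor the signal column given in the sources used here. The values are whole numbers from 39 to 65535, the scanner maximum, with unequal medians between arrays, so no normalization by the authors is visible. The plan made before the data were examined assumed values already normalized by the authors and kept quantile normalization as an alternative; since the values were raw, normexp background correction (offset 50) followed by quantile normalization and log2 became the normalization of every value, after seeing the data. The labels give the slide of each array and its block number (position) on that slide. Block number was in no model. Among males of each experiment the control arrays all shared a block number that no treated male array had. Position on the slide and gavage therefore cannot be told apart in males.

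The table held 15505 probes, of which 12544 carried 1 gene symbol, 2961 none and 0 several. All 12544 were looked up by Entrez identifier in RefSeq, used for names only, and 0 symbols changed. A gene with several probes (1869 genes, up to 12 probes) took the probe with the highest mean, which left 8996 genes. Probes at the scanner maximum were kept; 26 of the genes reached it on some array and 0 on all. Probes without a symbol were not used here. Symbols of the gene lists were matched through synonyms only where the symbol is not itself current, a correction made after results were first seen.

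Values were compared with limma 3.58.1 in R 4.3.3, with all arrays in 1 fit of 10 groups of sex and gavage (20 residual degrees of freedom), moderated by empirical Bayes. The 16 gene comparisons set each gavage against its own water controls, averaged over the sexes and in each sex, tested the difference between the sexes, compared G35 with G12 and with inulin, and compared females with males and control 2 with control 1 among the controls. A gene was called at an adjusted p (Benjamini-Hochberg over all genes tested) under 0.05. Each was refitted with slide as a random block (consensus correlation 0.386), and all but control 2 against control 1, where slides lie within experiments, with slide as a fixed block (12 residual degrees of freedom). Effects are log2 differences with the standard error of limma's fit.

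Before the data were examined, 46 gene lists for liver metabolism, immunity, stress, sex and cell types were fixed; 38 held at least 5 measured genes and were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the 38 lists, 9 comparisons), and the other 8, of which 3 had no measured gene, were too small. Each list was also tested with its correlation estimated from the data, and its members were also adjusted over the list alone. Named genes follow a rule fixed in advance: up to 10 called genes each way per averaged gavage comparison, filled to 5 with the lowest p of genes that point the same way in both sexes, 5 each way elsewhere, and up to 4 members per list. Applying the rule also to the fit with slide was decided after seeing the data.

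In the chicory experiment residuals of arrays with the same replicate number correlated at 0.123 to 0.709 (median 0.341, 18 pairs). Those of arrays with other numbers correlated at -0.528 to 0.393 (median -0.251, 36 pairs). Replicate number went with no higher correlation in the inulin experiment (-0.525 to 0.082 against -0.299 to 0.558). Among chicory arrays, 6 pairs with the same number on different slides correlated at 0.149 to 0.432. The 4 pairs with other numbers on the same slide lay at 0.109 to 0.393, against a median of -0.271 for pairs that share neither. Replicate 3 arrays lay on slides 1 and 2 and the others on slides 4 to 6, so number and slide are partly confounded. Within slides 4 to 6, pairs that share neither lay at -0.039 to 0.144. Much of the contrast therefore follows the sets of slides. A fit with replicate number as a block (12 residual degrees of freedom) is therefore given for the chicory comparisons where it changes a call.

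Settings varied as fixed in advance were leaving out each array, only the arrays of the groups compared, each array centred on its own median, limma's trend and robust options, leaving out the 25% dimmest genes, every probe, the replicate block and slide. Those added after seeing the data were 75th percentile scaling, cyclic loess, quantile normalization without background correction, median centring for lists, masking or leaving out a patch of low signal on the array of female G12 replicate 2, and all of these for the counts with slide in the model. The array layout used for the patch, 85 features per line by feature number, was chosen after the low features were seen, as the width at which they form a single block, and was not checked against a layout file. The bounds of the block enclose all features more than 2 log2 low on that array. The array of female control 2 replicate 1 also held 213 low features, clustered at 84.0% against 41.6% for random features; these were not masked, and only leaving out the whole array was run. Other splits of the same arrays were counted for each result (all splits up to 100, else 100 drawn with a fixed seed).

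The fit was tested on simulated data with known changes and with the gene spreads and slide correlation of these arrays. Slide effects were drawn separately for each gene, without the structure shared across genes that the first principal component of the real arrays shows. The false calls given here therefore do not measure what that structure adds. With 6 arrays against 6 it recovered 56.7% of changes of 0.5 log2 and 95.5% of changes of 1 log2, with 4 false among 172 calls, and with slide 64.2% and 97.0%. With 3 against 3 it recovered 29.9% and 77.6%. The simulation planted 67 changes of 0.5 log2, 67 of 1 log2 and 66 of 2 log2. With fewer true changes the Benjamini-Hochberg cutoff is stricter. These shares therefore do not hold for comparisons that called few or no genes. The median residual SD was 0.222 log2 without slide and 0.165 with it. Depth is not defined for arrays; the number of arrays limits the precision. None of the sex chromosome genes fixed for the check was measured. The contrast of control females with males covers control mice only, and its named genes were picked from that contrast. On the second principal component, however, all labelled males separated from all labelled females, treated mice included.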

Results

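Liver RNA of 30 mice was measured on one-colour (Cy3) Agilent arrays, with 1 array per mouse, so that replicates are separate animals per the labels. Mice that were 8 weeks old at the start were gavaged daily with 500 µl for 30 days. In the first experiment they received a decoction of chicory root flour, called G12 or G35, at 10 mg per mouse and day, or water (control 1). In the second, run afterwards, they received inulin, the fructan that chicory roots store, at 6.9 mg per mouse and day, which the labels match to the inulin in G35, or water (control 2). Each of the 10 groups of sex and gavage held 3 mice, so a comparison averaged over the sexes sets 6 treated mice against 6 controls. The arrays lay on 10 slides, 5 in each experiment. The median intensity per array ran from 141 in male inulin replicate 2 to 511 in male inulin replicate 3, and the number of arrays limits the precision.

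Slide and sex marked the first components of the spread between livers. The first principal component held 28.3% of the variance; slide accounted for 96.4% of it and experiment, within which the slides lie, for 60.4%. The second held 16.9%, and sex accounted for 82.6% of it. Comparisons are therefore given without and with slide in the model, except control 2 against control 1, and for gavages against their controls the main results also carry the number of sets of arrays of the same sex on the same slide that were higher.

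**Figure D1:**
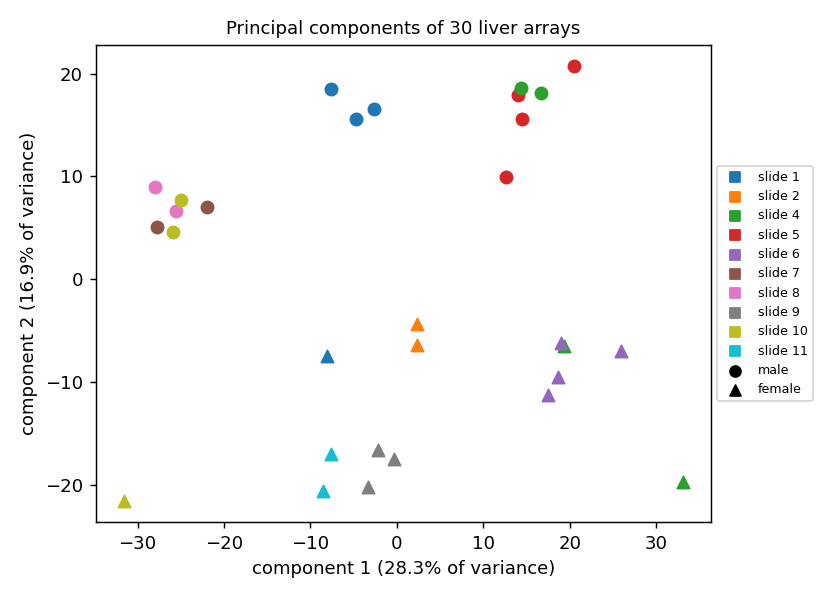
Each point is 1 of the 30 arrays, placed by its scores on principal component 1 (x axis, 28.3% of the variance) and principal component 2 (y axis, 16.9%) of the normalized log2 intensities, with slide and sex marked. Arrays of a slide mostly lie near each other along the x axis, though slides 4, 5 and 6 overlap. Female G12 replicate 2 stands at 33.1, apart from the other arrays of slide 4 (14.4 to 19.3). Females and males separate along the y axis.

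The first question was which liver transcripts differed between mice given the G35 decoction and their water controls. Averaged over the sexes, Saa3, an acute phase serum amyloid, rose by 0.93 ± 0.17 log2 (SE, 6 mice against 6) and Nfil3, a transcription factor tied to the circadian clock, rose by 0.94 ± 0.16. Inhbb, which encodes an activin and inhibin subunit, rose by 0.72 ± 0.11 and C9orf72 by 0.63 ± 0.10, while Hdhd3, a hydrolase domain protein, fell by 0.75 ± 0.13. Most of the C9orf72 rise came from males, with means of 7.82 in control 1 and 8.90 in G35, against 7.76 and 7.94 in females. The difference between the sexes was not called for this gene. These 5 of the 8996 genes tested passed, with adjusted p from 0.00448 for Inhbb to 0.0259 for Saa3. The 4 genes that rose were higher in 4 of 4 sets of arrays of the same sex and slide, and Hdhd3 was higher in 0 of 4. Next in order came Mrtfb at 0.59 ± 0.12 (adjusted p = 0.0554), and, below the controls but not passing, Ppp1r35, Kank2, Tnfrsf19 and Fadd, from -0.35 to -0.53 (adjusted p from 0.103 to 0.218). With replicate number as a block, 3 genes passed, Nfil3, Saa3 and Inhbb (adjusted p = 0.0199 for each), while C9orf72 had an adjusted p of 0.0819 and Hdhd3 of 0.0724. Inhbb passed without each of the 12 arrays in turn. Fitted on only the arrays of the groups compared, none of the 5 passed (adjusted p of Inhbb and Nfil3 0.0948, of Saa3, C9orf72 and Hdhd3 0.237), and 3 genes passed with median centring or 75th percentile scaling. The calls of Nfil3, Saa3, C9orf72 and Hdhd3 all ended without male control 1 replicate 2, male control 1 replicate 3 or female G35 replicate 3, which left 1 gene each. Those of Nfil3, Saa3 and Hdhd3 also ended without male G35 replicate 3 (2 genes left), those of Nfil3 and Hdhd3 without female G35 replicate 1 (3 genes left), and that of Saa3 without male G35 replicate 2 or female control 1 replicate 1 or 2. Adjusted p of the ended calls ran from 0.0524 for Nfil3 to 0.130 for Saa3. More genes passed without male control 1 replicate 1 (14), female control 1 replicate 3 (9) or female G35 replicate 2 (8).

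**Figure D2:**
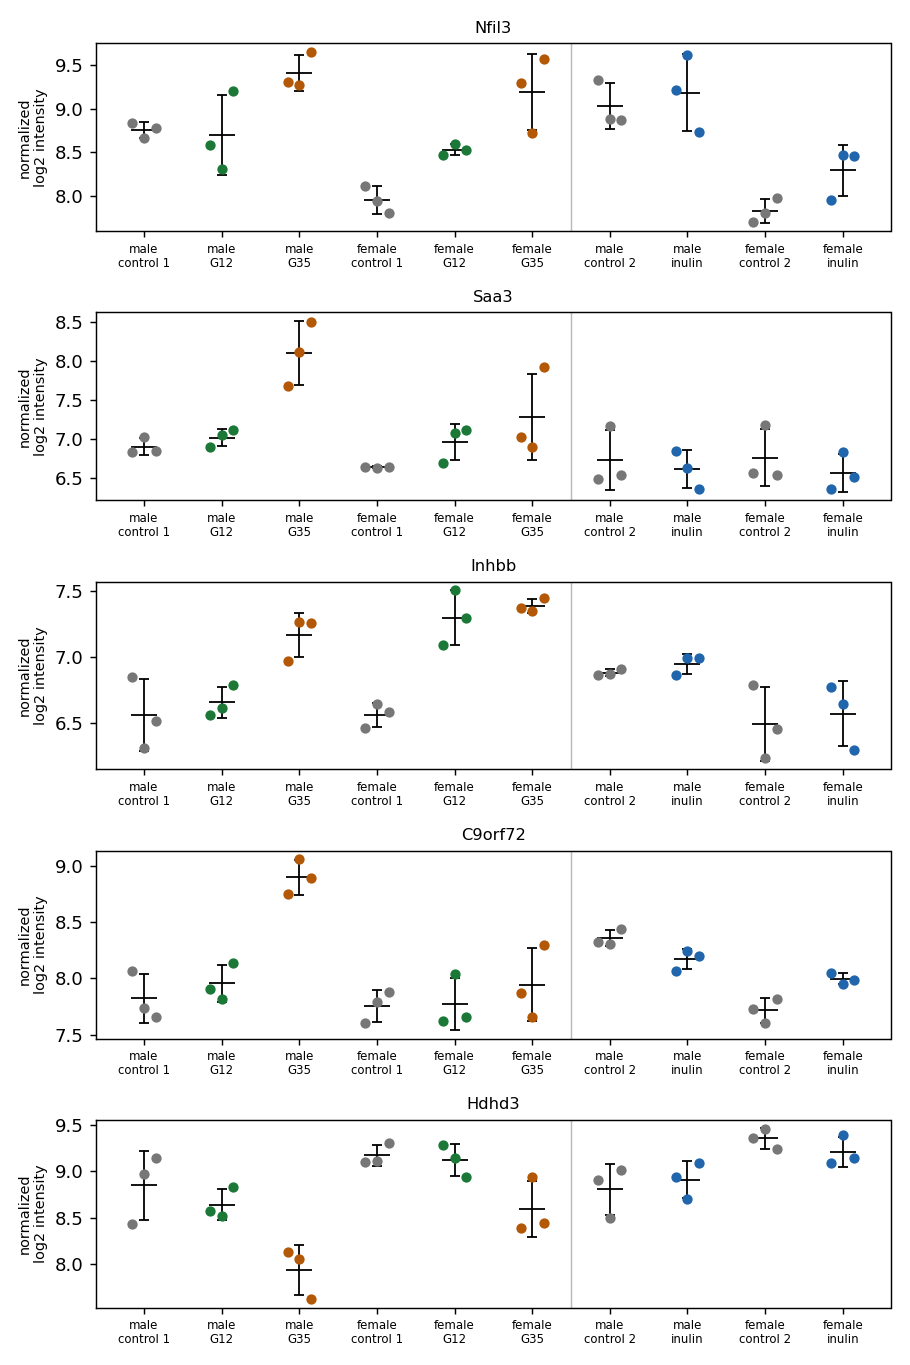
Normalized log2 intensity (y axis) of the 5 genes that passed under G35 in each of the 10 groups of 3 mice (x axis). Points are mice and bars give the mean ± SD, and the G35 groups lie above control 1 for Nfil3, Saa3, Inhbb and C9orf72 and below it for Hdhd3.

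Under G35, 41 genes passed with slide in the model, 27 higher and 14 lower, and 4 of the 5 genes above were among them; 33 passed with slide as a random block and 5 with slide and replicate number together. Hdhd3 was then at -0.70 ± 0.15 (adjusted p = 0.0516). Genes that rose in this model included Nr1i2, which encodes the xenobiotic receptor PXR (0.95 ± 0.18), Mbnl2, a regulator of splicing (0.92 ± 0.10), and Vcam1, an adhesion molecule of activated endothelium (0.82 ± 0.13), with adjusted p of 0.0312, 0.000779 and 0.0104. Bcl3, Impact and Pnrc1 rose by 0.68 to 0.77. Rnf43, an inhibitor of Wnt signalling, fell by 0.74 ± 0.12 and Aatf by 0.70 ± 0.11, with adjusted p of 0.0179 and 0.0104. Hcn2, Scn3b, Hspg2, Ppp1r35, Dynlrb1, S1pr1, Tnrc18 and Rrp36 were also lower, from -0.49 to -1.10. The count in this model was 465 without female control 1 replicate 1, 126 without female G35 replicate 2 and 63 without male control 1 replicate 1. It was 27 without male G35 replicate 2, 23 without male G35 replicate 1, 9 without female G35 replicate 1, 6 without male control 1 replicate 3 or female G35 replicate 3, and 3 without male G35 replicate 3.

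All 8 of the 38 gene lists that passed under G35 were higher, with the lowest p at the preset correlation for acute phase, ER stress, heat shock and complement genes. The acute phase list averaged 0.69 log2 above control 1, with 24 of its 25 measured members higher (adjusted p = 1.45e-11). The adjusted p was 0.249 with an estimated correlation and 6.38e-08 with slide in the model, and the list was higher in 4 of 4 sets of arrays of the same sex and slide, by 0.24 to 1.12. Adjusted over the list alone, 5 members passed, Saa3, Saa1 (3.43 ± 0.93), Saa2 (2.92 ± 0.80), Apcs (1.07 ± 0.34) and Steap4 (0.55 ± 0.19), against 1 over all genes. Saa1 was uneven, from 9.35 to 15.66 in female and from 10.88 to 15.36 in male G35, and also reached 15.04 in male control 2. The ER stress list averaged 0.25 higher with 17 of 19 members up (adjusted p = 1.01e-05, 0.00801 with slide), and Herpud1, a gene of ER protein degradation, passed over the list alone at 0.51 ± 0.13. The heat shock list averaged 0.20 higher (adjusted p = 4.87e-05, 0.118 with slide) and the complement and coagulation list 0.15 higher with 26 of 30 members up (adjusted p = 0.000827, 0.0465 with slide). In that order the adjusted p of these 3 lists was 0.255, 0.251 and 0.332 with an estimated correlation. All 4 lists kept their calls without each of the 12 arrays in turn. Inflammatory cytokines and chemokines averaged 0.26 higher (Cxcl1 at 1.07 ± 0.34), cholesterol synthesis 0.20 (Insig1 at 0.41 ± 0.21), Kupffer cell and macrophage markers 0.19 (C1qb at 0.29 ± 0.14) and antimicrobial and innate sensing genes 0.35 (Lcn2 at 2.11 ± 0.78, Cd14 at 0.51 ± 0.13). Their adjusted p was 0.00782, 0.00191, 0.00367 and 0.0331, was 0.251, 0.505, 0.362 and 0.249 with an estimated correlation, and lay between 0.0626 and 0.182 with slide in the model. The inflammatory list lost its call without female control 1 replicate 2 (adjusted p = 0.0641), cholesterol synthesis without male G35 replicate 1 (0.0971) or female control 1 replicate 3 (0.0511), and the macrophage list without female control 1 replicate 1 (0.0542) or 2 (0.0536). The antimicrobial list lost its call without male control 1 replicate 1 or 3 or female control 1 replicate 1 or 2 (0.0666 to 0.149). The count of lists was 5 without female control 1 replicate 2.

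The same question was asked for G12. Lifr, the receptor of leukemia inhibitory factor, had the lowest unadjusted p, at -0.80 ± 0.15 log2 (SE, 6 mice against 6), lower than control 1 in each of the 4 sets of arrays of the same sex and slide. Its adjusted p was 0.240, against 0.0200 with slide in the model and 0.00899 with replicate number as a block. Aatf was at -0.64 ± 0.14, and at -0.67 ± 0.10 (adjusted p = 0.0272) with slide. Slc29a1, Armc6 and Fbxl6 lay from -0.33 to -0.56, and Ythdc1, Kctd2, Zkscan1, Hspa4l and Inhbb from 0.42 to 0.45, with adjusted p from 0.467 to 0.753. With limma, 0 genes passed over all genes, 467 had an unadjusted p under 0.05 where 450 were expected by chance, and 0 passed without each of the 12 arrays in turn. Counts were 3 with slide in the model (Lifr, Aatf and Hspg2), 1 with slide as a random block and 1 with replicate number as a block. Hspg2 lies inside a patch of low signal on the array of female G12 replicate 2. The averaged fit with slide was not run with that patch masked.

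Chaperones had the lowest p of the lists that passed under G12, of which 4 were higher and 3 lower. The heat shock list averaged 0.18 higher with 13 of 16 members up (adjusted p = 0.000416, 0.118 with slide, higher in 3 of 4 sets), kept its call without each of the 12 arrays in turn, and held 1 gene that passed over the list alone, Hspa4l (0.44 ± 0.11). ER stress genes averaged 0.14 higher, fatty acid oxidation and PPAR-alpha targets 0.13 and proteasome genes 0.09, while interferon response genes averaged -0.11 (18 of 24 lower), stellate cell and fibroblast markers -0.10 and erythroid markers -0.23. These 6 lists had adjusted p from 0.0173 to 0.0494, and the adjusted p of all 7 was 0.590 with an estimated correlation. The pancreas genes Ctrb1 (3.69 ± 1.29) and Amy2a5 (1.88 ± 0.57) also stood higher under G12, without passing (adjusted p = 0.887 and 0.846). With slide in the model the interferon and proteasome lists passed (adjusted p = 0.0472 for each), and interferon genes were higher in 0 of 4 sets. Each of the 6 lost its call without some array, and all of them without female G12 replicate 3 (adjusted p from 0.112 to 0.514), which left 1 list. Counts of lists were also 1 without male G12 replicate 3, 4 without male control 1 replicate 2 and 4 without female control 1 replicate 1.

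Inulin was compared with its own water controls, at the dose matched to the inulin of G35. No gene moved past the threshold. Tacr2, a tachykinin receptor, was at 0.69 ± 0.21 log2 (SE, 6 mice against 6), Wdr13 at 0.83 ± 0.26, Haus4 at 0.79 ± 0.25, Myh9 at 0.45 ± 0.13 and Tardbp at 0.41 ± 0.12. Pfkfb3, a regulator of glycolysis, was at -0.62 ± 0.18, and Slc23a1, Cnpy2, Anks1 and Dnttip1 lay from -0.26 to -0.42. All of these had an adjusted p of 1.00, and limma called 0 genes with 179 at an unadjusted p under 0.05 (450 expected). A set of 4 genes passed with slide in the model (adjusted p = 0.0455 for each): Tacr2 (0.81 ± 0.12) and Lhx6 (0.77 ± 0.13) higher in 5 of 5 sets of arrays of the same sex and slide, and Skint7 (-0.82 ± 0.13) and Llph (-0.43 ± 0.07) higher in 0 of 5. Slide as a random block called 0 genes (lowest adjusted p = 0.394). Without slide, 9 genes passed once male control 2 replicate 1 was left out and 4 once male inulin replicate 3 was.

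Chaperones and erythroid markers moved in opposite directions under inulin. The heat shock list averaged 0.26 higher, with 14 of 16 members up (adjusted p = 7.10e-10). Its adjusted p was 0.0653 with an estimated correlation and 1.64e-06 with slide, and it was higher in 4 of 5 sets. The cochaperones Dnaja1 and Bag3 stood at 0.47 ± 0.15 and 0.36 ± 0.13, and the heat shock proteins Hsph1 and Hsp90aa1 at 0.47 ± 0.16 and 0.49 ± 0.19. Erythroid markers averaged -0.33, with 8 of 8 members lower, among them the globin genes Hba-a2 (-0.37 ± 0.14) and Hbb-b2 (-0.56 ± 0.25). Nearly all of this fall came from females, where the erythroid list stood at -0.60 ± 0.22, against -0.05 ± 0.22 in males. The adjusted p of this list was 0.000332, 0.271 with an estimated correlation and 0.000230 with slide, and it was higher in 1 of 5 sets. Both lists kept their calls without each of the 12 arrays. Cholesterol synthesis averaged 0.18 higher with 16 of 18 members up (adjusted p = 0.000332, 1.64e-06 with slide, higher in 5 of 5 sets), and cytochrome P450 genes 0.12 higher (adjusted p = 0.0258, 0.424 with slide). The adjusted p of each of these lists was 0.550 with an estimated correlation. Cholesterol synthesis lost its call without female control 2 replicate 3 (0.275) or female inulin replicate 1 (0.106). The P450 list lost its call without male control 2 replicate 3, male inulin replicate 2 or 3, female control 2 replicate 1 or female inulin replicate 1 (0.0677 to 0.449). The count of 4 lists became 9 without male control 2 replicate 1.

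**Figure D3:**
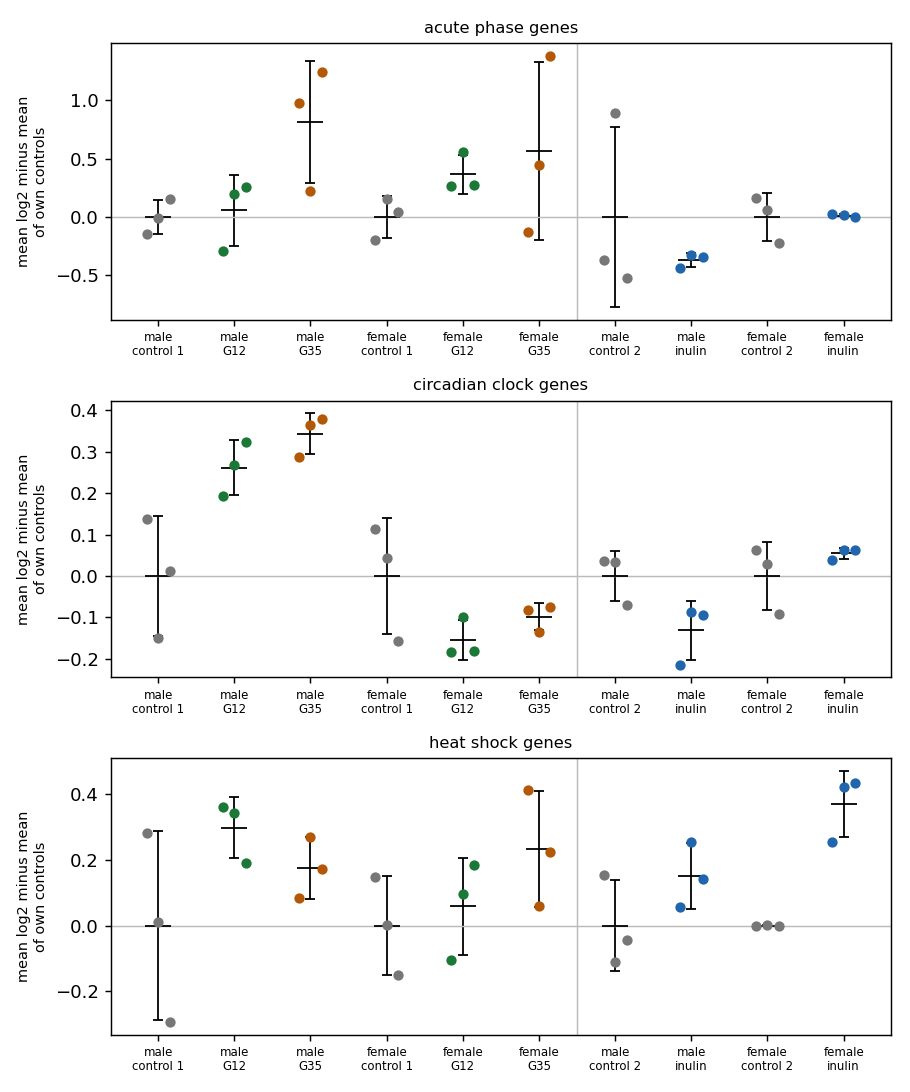
Mean log2 intensity of the acute phase, circadian clock and heat shock lists in each mouse, minus the mean of its own water controls of the same sex (y axis, log2), for each sex and gavage (x axis, 3 mice per group, bars mean ± SD). The acute phase list of the G35 mice runs from 0.23 to 1.24 in males and from -0.13 to 1.38 in females.

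In males alone, C9orf72 rose under G35 by 1.08 ± 0.15 log2 (SE, 3 mice against 3; adjusted p = 0.00138, 0.00205 with slide), higher in 3 of 3 slides, and passed without each of the 6 arrays in turn, though not when only the arrays of these groups were fitted (adjusted p = 0.182). It was the 1 gene called. All male control 1 arrays shared a block number that no male G35 array had, so position on the slide cannot be told apart from G35 here. With slide in the model 32 genes passed, 26 higher and 6 lower; 42 passed with slide as a random block and 0 with slide and replicate number together, which ended all 32 calls. The largest rise was in Ppp1r3g, a glycogen-targeting phosphatase subunit, at 3.15 ± 0.52 (adjusted p = 0.0206, 0.0780 without slide). Plk3 (1.64 ± 0.32), Irf2bp2 (1.44 ± 0.18), Trp53inp1, a p53-induced gene (1.37 ± 0.24), and Igfbp1, a hepatic IGF binding protein (1.25 ± 0.26), rose as well, with adjusted p from 0.00205 to 0.0471. The Igfbp1 mean of 12.28 in male control 1 was the lowest of the 10 groups (12.68 to 13.70 in the others). Cyp3a44 (-1.36 ± 0.27), Rnf43 (-1.04 ± 0.15), the glycogen-targeting subunit Ppp1r3c (-0.94 ± 0.19), Hdhd3 (-0.92 ± 0.19) and Gstm2 (-0.65 ± 0.13) fell, with adjusted p from 0.00962 to 0.0471. Replicate number as a block gave 9 genes. The count without slide was 8 without male control 1 replicate 1, 4 without male G35 replicate 1 and 3 without male G35 replicate 3. With slide it was 6 without male control 1 replicate 2, 2 without male control 1 replicate 3, and 4 without male G35 replicate 2 or 3.

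Under G35 in males 13 lists passed, 12 of them higher. The circadian clock list averaged 0.34 higher with 13 of 17 members up (adjusted p = 1.37e-05, 0.00632 with an estimated correlation, 0.000114 with slide, but 0.212 with both, which ends the call), higher in 3 of 3 slides by 0.15 to 0.51. Over the list alone 5 members passed, against 0 over all genes: Noct (1.01 ± 0.24), Per1 (0.98 ± 0.20), Usp2 (0.72 ± 0.27), Nfil3 (0.65 ± 0.23) and Bhlhe40 (0.62 ± 0.23). Acute phase genes averaged 0.81 higher (22 of 25 up; adjusted p = 4.55e-08), cholesterol synthesis 0.43 (16 of 18 up; 4.34e-06), complement and coagulation 0.24 (27 of 30 up; 6.70e-05) and ER stress 0.24 (16 of 19 up; 0.000329). With an estimated correlation the adjusted p of these 4 was 0.214, 0.283, 0.215 and 0.294, with slide it ran from 3.47e-07 to 0.000221, and all 5 lists kept their calls without each of the 6 arrays. Immediate early genes averaged 0.40 higher (adjusted p = 0.000669, 0.200 with an estimated correlation), with Maff at 0.87 ± 0.26. Genes of gluconeogenesis and glycogen averaged 0.34 higher with 10 of 16 members up (adjusted p = 0.0178, 0.200 with an estimated correlation); over the list alone Ppp1r3g and Foxo1 (0.91 ± 0.23) passed upward and Ppp1r3c downward. Without male G35 replicate 2 the adjusted p was 0.0511 for immediate early genes and 0.149 for gluconeogenesis. The other 6 lists were heat shock, PPAR-alpha targets, insulin and growth hormone axis, inflammatory cytokines and antimicrobial genes, all higher, and proteasome genes at -0.13. Their adjusted p was 0.0120 to 0.0412, was 0.200 to 0.502 with an estimated correlation, and each lost its call without 2 to 5 of the 6 arrays. The count of lists was 8 without male control 1 replicate 3 and 7 without male G35 replicate 2.

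Male-biased genes and the clock moved in males given G12. The list of major urinary proteins and other male-biased genes averaged -0.43, with 13 of 13 members lower (adjusted p = 1.51e-05, 0.0589 with an estimated correlation, 1.17e-06 with slide), and Susd4 (-0.77 ± 0.21) and Nudt7 (-0.77 ± 0.22) passed over the list alone. The clock list averaged 0.26 higher with 14 of 17 members up (adjusted p = 0.000363, 0.0293 with an estimated correlation, 0.000457 with slide, but 0.191 with both, which ends the call), and Per1 (0.87 ± 0.20) and Noct (0.84 ± 0.24) passed over the list alone. Both lists kept their calls without each of the 6 arrays. Heat shock genes averaged 0.30 higher (14 of 16 up; adjusted p = 1.09e-05, 0.152 with an estimated correlation, 9.63e-05 with slide), with Hsph1 at 0.81 ± 0.23. Cytochrome P450 genes averaged -0.23 (16 of 22 lower; adjusted p = 0.00292, 0.469 with an estimated correlation, 0.0377 with slide), among them Cyp2c37 (-0.95 ± 0.28). PPAR-alpha targets averaged 0.18 higher (adjusted p = 0.0102, 0.564 with an estimated correlation, 0.00646 with slide), led by Cyp4a14 (0.90 ± 0.23). The heat shock call ended without male control 1 replicate 3 (0.0534), the P450 call without male G12 replicate 1 (0.282) and the PPAR-alpha call without male G12 replicate 2 (0.335). Urea cycle genes (-0.17), ER stress (0.16) and cholesterol synthesis (0.24) passed at adjusted p from 0.0216 to 0.0437, had 0.564 to 0.590 with an estimated correlation, and each lost the call without 2 to 4 of the 6 arrays. Without male G12 replicate 1, 13 lists passed in place of 8. The pancreas genes Ctrb1 (6.04 ± 1.82) and Amy2a5 (2.46 ± 0.80) also stood higher in these males, without passing (adjusted p = 0.790 and 1.00). Of single genes, limma called 0 in males given G12, with 353 at an unadjusted p under 0.05, and 0 in every other fit run for this comparison.

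In males given inulin, cholesterol synthesis averaged 0.26 higher (16 of 18 up; adjusted p = 0.00639, 0.0421 with slide) and was higher in 3 of 3 slides, and acute phase genes averaged -0.37 (19 of 25 lower; adjusted p = 0.00679, 0.0429 with slide) but were higher in 2 of 3 slides. ER stress (0.17), interferon response (-0.14) and gluconeogenesis (-0.18) also passed, at adjusted p from 0.0182 to 0.0450. With 75th percentile scaling the interferon list had a mean of 0.00. With an estimated correlation the adjusted p of all 5 lists was 0.711. All 5 calls ended without male control 2 replicate 2 (acute phase at 0.761) or without male inulin replicate 3. Counts were 3 without male inulin replicate 1 and 9 without male inulin replicate 2. In the male controls of that experiment Saa1 ranged from 8.82 to 15.04. For single genes limma called 0, with 186 at an unadjusted p under 0.05, and 15 without male control 2 replicate 1 or male inulin replicate 3; slide as a random block called 1.

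In females given G12, 5 genes fell: Tob2, an antiproliferative gene, by 1.83 ± 0.27 log2 (SE, 3 mice against 3), Hspg2, which encodes the matrix proteoglycan perlecan, by 1.58 ± 0.28, Aatf by 1.13 ± 0.20, Celf1, an RNA-binding protein, by 0.71 ± 0.13, and Pfkl, liver phosphofructokinase, by 0.63 ± 0.11. Adjusted p ran from 0.00435 to 0.0250, each gene was higher in 0 of 2 sets of arrays of the same sex and slide, and with slide in the model all 5 passed. With replicate number as a block only Tob2 passed, and on only the arrays of these groups 0 genes did. The Tob2 mean of 9.82 in female control 1 lay above the 7.74 to 8.77 of the other 9 groups, 8.12 in female control 2 among them, so these controls stand apart. Tob2 and Hspg2 lie inside a patch of low signal on the array of female G12 replicate 2. With that patch masked, Tob2 was at -1.62 (adjusted p = 0.0305) and Hspg2 at -1.06 (0.0513). Without that array 0 genes passed. The count was also 1 without female control 1 replicate 1, 3 without female G12 replicate 1 and 33 without female control 1 replicate 2. The calls of Hspg2, Aatf, Celf1 and Pfkl ended without female control 1 replicate 1 (0.150 to 0.172), that of Celf1 without female control 1 replicate 3 (0.126), those of Celf1 and Pfkl without female G12 replicate 1 (0.0503), and that of Aatf without female G12 replicate 3 (0.0578).

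In G12 females 400 genes passed with slide in the model, 132 higher and 268 lower, against 101 with slide as a random block and 2 with slide and replicate number together. Insig2, which retains sterol-sensing complexes in the ER, rose by 0.99 ± 0.24, Tdo2, tryptophan dioxygenase, by 0.94 ± 0.22, Cnbp by 1.09 ± 0.27 and Zfp207 by 0.95 ± 0.21, all higher in 2 of 2 sets. Of the 268 lower genes, 139 lay inside the patch, Gabarapl1 and Chchd10 among them; its bounds were drawn around the low features of that array, which places the largest falls there by construction. Leaving aside genes whose own feature was that low, 67 of 196 lower genes lay inside it, where 5.35 were expected. With the patch masked 167 genes passed, 79 higher and 88 lower. The count was 82 without female control 1 replicate 2 and 210 without female control 1 replicate 3. Without any other array, that of female G12 replicate 2 with the patch included, it stayed within 1.5 times of 400, with 579 as the highest. No list passed in G12 females with limma's camera, which found 0 lists with slide and with an estimated correlation too, 2 with replicate number as a block, and 1 or 2 without female control 1 replicate 2 or 3 or female G12 replicate 1 or 2.

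**Figure D4:**
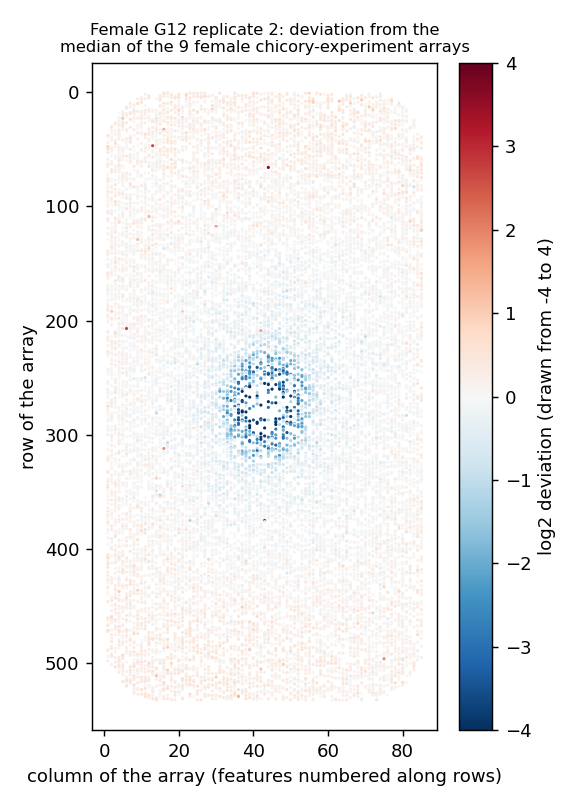
Map of the array of female G12 replicate 2, with each feature at its column (x axis) and line (y axis) in the order of feature numbers at 85 per line, a width chosen after the low features were seen, coloured by its log2 deviation from the median of the 9 female arrays of the chicory experiment. All 213 features more than 2 log2 units low lie in a block of 87 by 24 positions.

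In females given G35 the acute phase list averaged 0.56 higher, with 23 of 25 members up (adjusted p = 6.11e-05, 0.746 with an estimated correlation, 0.00364 with slide). Heat shock genes averaged 0.23 higher, ER stress 0.26 and macrophage markers 0.23 (12 of 12 up), with adjusted p of 0.00448, 0.0139 and 0.0139, 0.746 with an estimated correlation, and 0.605, 0.459 and 0.247 with slide. Without female G35 replicate 3 the acute phase (0.419), ER stress (0.588) and macrophage (0.419) calls ended. The heat shock call ended without female control 1 replicate 3 (0.181) or female G35 replicate 1 (0.250), the ER stress call also without female control 1 replicate 1 (0.216), and the macrophage call also without female control 1 replicate 1 (0.390) or 2 (0.372). No single gene passed without slide (limma, 0 called, 724 at an unadjusted p under 0.05; 5 without female control 1 replicate 2 and 1 without female G35 replicate 2). With slide 77 did, 30 higher and 47 lower, against 4 with slide as a random block and 2 with slide and replicate number together, so nearly all of these calls end under other blocks. Among the 77 were Nr1i2 (1.44 ± 0.28), the lipoprotein lipase gene Lpl (1.13 ± 0.25), Mbnl2 (1.11 ± 0.16) and Vcam1 (1.02 ± 0.20), and, lower, Lzts3, Shc4, Cd300lf, Scn3b and Cabp5 from -1.97 to -2.16. Only 1 slide carried female arrays of both groups. The count of 77 was 402 without female control 1 replicate 1, 29 without female control 1 replicate 2, and 2, 15 and 27 without female G35 replicates 1, 2 and 3.

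In females given inulin, heat shock genes averaged 0.37 higher, with 13 of 16 members up (adjusted p = 1.30e-08, 0.113 with an estimated correlation, 1.80e-06 with slide), higher in 2 of 2 sets, and kept the call without each of the 6 arrays. Over the list alone 5 members passed, Hsp90aa1 (0.81 ± 0.27), Dnajb1 (0.78 ± 0.27), Dnaja1 (0.71 ± 0.21), Bag3 (0.69 ± 0.19) and Hspe1 (0.41 ± 0.15), against 0 over all genes. Erythroid markers averaged -0.60 with 7 of 8 lower (adjusted p = 8.75e-05, 0.173 with an estimated correlation, 2.35e-06 with slide), and Hba-a2 (-0.84 ± 0.20) and Hbb-b2 (-0.97 ± 0.35) passed over the list alone. Without female control 2 replicate 3 the erythroid call ended (0.0540) and 1 list was left. The array of female control 2 replicate 1 carried 213 low features, 84.0% with a low neighbour against 41.6% of random features; without it 3 lists and 0 genes passed. Counts were 4 to 6 without female control 2 replicate 2 or any of the female inulin mice. For single genes limma called 0 in each fit, with 328 at an unadjusted p under 0.05 (618 with slide).

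Whether the sexes responded differently was tested gene by gene, and not for lists. The male part of each difference carries the position on the slide, which cannot be told apart from gavage in males. The G12 effect was lower in females than in males for Tob2, by -2.25 ± 0.38 log2 (SE; adjusted p = 0.0275, 0.0174 with slide), and for Pfkl, by -0.87 ± 0.15 (0.0275, 0.0217 with slide). The G35 effect was higher in females for Slc25a4, a mitochondrial ADP/ATP carrier, by 1.65 ± 0.30, and lower for the clock gene Per1, by -1.60 ± 0.28 (adjusted p = 0.0437 for each, 0.0825 for each with slide). Per1 averaged 8.04 in male and 9.49 in female control 1 and 9.03 and 8.87 in the corresponding G35 groups. These control means were the lowest and the highest of the 10 groups. With slide, 63 genes differed for G12, 15 of them more positive in females, such as Insig2 (1.93 ± 0.34), and 0 for G35. No gene passed for inulin (limma, 0 called, 302 at an unadjusted p under 0.05). Replicate number as a block gave 0 genes for G12, 0 for G35 and 1 for inulin, and fitting only the arrays of the groups compared gave 0 for each. With the patch masked 0 genes passed for G12 (adjusted p = 0.0569 for Tob2 and Pfkl), though Pfkl lies outside the patch and its own values were unchanged. The calls of Tob2 and Pfkl both ended without any of the male control 1 mice, male G12 replicate 1, female control 1 replicate 1 or 3, or female G12 replicate 1 or 2 (adjusted p from 0.0519 to 0.171), which left 0 genes, or 1 without female G12 replicate 2; 6 passed without male G12 replicate 2 and 52 without female control 1 replicate 2. Those of Per1 and Slc25a4 both ended without any of the 6 G35 mice or female control 1 replicate 1 or 3, which left 0 genes, that of Per1 also without male control 1 replicate 1 or 2, and that of Slc25a4 without female control 1 replicate 2 (0.0587 to 0.187). For inulin 1 gene passed without male control 2 replicate 1 and 10 without male inulin replicate 3.

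G35 and G12 were then set against each other, each with 6 mice. A total of 8 genes differed with slide in the model, 6 higher under G35 and 2 lower. Saa3 was higher under G35 by 0.70 ± 0.12 log2 (SE; adjusted p = 0.0374), C9orf72 by 0.61 ± 0.10 and Mbnl2 by 0.59 ± 0.09 (0.0311 for each), the cAMP-responsive regulator Crem by 0.56 ± 0.10 and Cope, a coatomer subunit, by 0.49 ± 0.09. Rnf43 was lower by -0.82 ± 0.12 (0.0104) and Kctd2 by -0.47 ± 0.08 (0.0455). Without slide limma called 0 genes, with 408 at an unadjusted p under 0.05 and C9orf72 closest at 0.56 ± 0.10 (adjusted p = 0.0783). Slide as a random block gave 10 genes, replicate number as a block gave 0, and 9 passed without female G35 replicate 2 and 1 without female G12 replicate 2.

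The G35 effect was also compared with the inulin effect, which asks what the decoction does beyond its matched inulin, across experiments run one after the other. Here 5 genes differed with slide in the model: Saa3 by 1.14 ± 0.18 and Mbnl2 by 0.95 ± 0.14 more positive under G35, and Pdcd4, a translation inhibitor, by -1.17 ± 0.19, Tacr2 by -1.17 ± 0.18 and Lhx6 by -1.16 ± 0.18 more negative (adjusted p = 0.0218 to 0.0219). Without slide limma called 0, with 259 at an unadjusted p under 0.05; Saa3 was then at 1.08 ± 0.24 (adjusted p = 0.610). Slide as a random block gave 1 gene, replicate number as a block gave 0, and 2 genes passed without male control 2 replicate 1 or male inulin replicate 3.

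Control females and males differed in 486 genes, 234 higher in females and 252 lower, several cytochrome P450 genes among them. Cyp2b13 was higher in females by 5.34 ± 0.24 log2 (SE, 6 mice against 6), Cyp3a44 by 5.18 ± 0.22, the hepcidin gene Hamp2 by 4.26 ± 0.34, Cyp3a41b by 2.40 ± 0.37 and Ly6c1 by 2.21 ± 0.31. Lower in females were Susd4 (-4.05 ± 0.15), Pax2 (-3.94 ± 0.22), Nat8 (-3.74 ± 0.21), the oxysterol hydroxylase Cyp7b1 (-3.25 ± 0.22) and Cyp2d9 (-2.82 ± 0.24). Adjusted p ran from 2.51e-15 to 0.000164, all 10 passed without each of the 12 arrays, and with slide in the model all 10 passed among 1139 genes.

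The control mice of the second experiment differed from those of the first in 2058 genes, 1228 higher and 830 lower (6 mice against 6). The nuclear long noncoding RNA Neat1 was higher by 2.23 ± 0.36 log2 (SE), Cyp2d37-ps by 2.12 ± 0.42, the apolipoprotein gene Apoa4 by 1.83 ± 0.36, Ccnl2 by 1.65 ± 0.35 and Clec2d by 1.56 ± 0.49. Lower were Iqsec3 (-3.48 ± 0.69), Magef1 (-3.03 ± 0.87), Vax2 (-2.76 ± 0.98), Knstrn (-2.24 ± 0.70) and Pzp, a protease inhibitor of plasma (-2.11 ± 0.68), with adjusted p of all 10 from 0.000214 to 0.0447. The call of Clec2d ended without male control 1 replicate 2, female control 1 replicate 2, male control 2 replicate 3 or female control 2 replicate 2, and that of Knstrn without male control 1 replicate 1, female control 1 replicate 1 or male control 2 replicate 1. That of Pzp ended without male or female control 1 replicate 1 or 2, male control 2 replicate 2 or female control 2 replicate 1, and that of Vax2 without 9 of the 12 arrays, all but male and female control 1 replicate 3 and female control 2 replicate 2 (adjusted p of these from 0.0503 to 0.130). No slide carried both experiments, so slide and experiment cannot be told apart here; slide as a random block gave 1642 genes.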

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

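The tests of the patch, of slide for both gene lists, of time of day in G12 males and of T, NK and neutrophil markers were chosen after the result was seen; those of time of day in G35 males, glucocorticoid targets, single mice and the splits were fixed before.

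The G12 effect on Tob2 differed between the sexes by -2.25 ± 0.38 log2 (female minus male; adjusted p = 0.0275), with means of 9.82 in female control 1 and 7.99 in female G12 against 8.31 and 8.73 in males. That on Pfkl differed by -0.87 ± 0.15 (adjusted p = 0.0275), from 7.70 to 7.07 in females and from 7.29 to 7.54 in males. The G35 effect on Per1 differed by -1.60 ± 0.28 (adjusted p = 0.0437), from 9.49 to 8.87 in females and from 8.04 to 9.03 in males. That on Slc25a4 differed by 1.65 ± 0.30 (adjusted p = 0.0437), from 9.80 to 10.74 in females and from 9.93 to 9.22 in males. All 4 lost their calls without some arrays, with replicate number as a block (adjusted p = 0.0573 to 0.209) and on only the arrays of the groups compared (0.0948 to 0.688). Tob2 and Pfkl also lost theirs with the patch masked (0.0569), and Per1 and Slc25a4 with slide in the model (0.0825). Pfkl lies outside the patch, so the mask left its own values unchanged and moved its adjusted p only through other genes. The Tob2 mean of 9.82 in female control 1 stands above the 7.74 to 8.77 of the other 9 groups. The Per1 means of control 1, 9.49 in females and 8.04 in males, were the highest and lowest of the 10 groups. The other groups lay at 8.31 to 9.13, so a trait of these controls stays open for Per1 as well.

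The large set of lower genes in G12 females with slide in the model has a technical part. Of 268 lower genes, 139 lay inside a block of low signal on the array of female G12 replicate 2, drawn around its lowest features, and only 5 of them were still called once the block was masked. Masking also takes 1 of the 3 female G12 arrays from these genes. Higher genes, 0 of which lay inside, fell from 132 to 79 with the mask too, so lost calls alone do not show lost signal. Features inside the block that were not used to draw it were also low on that array (median -0.96 log2, against -0.04 to 0.14 on the other 8 female chicory arrays), and 67 lower genes were among them where 5.35 were expected, which is consistent with lost signal on 1 array. With the block masked 88 genes remained lower, so lost signal there does not account for them. Whether G12, slide or another structure of these 6 arrays lies behind those 88 stays open, and no other splits were counted with the block masked.

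The clock list was higher in males under both decoctions, with Per1 and Noct in front, while in females it stood at -0.15 ± 0.07 (G12) and -0.10 ± 0.07 (G35), without passing. Offsets between whole slides cannot give the G35 difference in males, since each of the 3 slides held 1 mouse of each group and the list was higher by 0.15 to 0.51 within each. Its call ended with slide and an estimated correlation together (adjusted p = 0.212, and 0.191 in G12 males). All male control 1 arrays shared a block number on their slides that no male G12 or G35 array had, so position on the slide stays open. Another time of day for the controls stays open: the clock output genes averaged 0.03 ± 0.09 in G35 males and 0.17 ± 0.09 in G12 males, but they go both ways and peak at different phases, so a mean near 0, set in advance to argue against it, decides nothing, and in G35 females they stood at -0.22 ± 0.09. Glucocorticoid targets averaged 0.40 ± 0.15 in G35 males and 0.31 ± 0.15 in G12 males, so a glucocorticoid response to handling or fasting may contribute, though none of the 9 passed and they were uneven (in G35 males Zbtb16 1.14, Tsc22d3 0.55, Fkbp5 0.05, Sgk1 -0.02). Both comparisons share the 3 male control 1 mice, whose Noct mean of 8.91 lay under the 9.48 to 10.59 of the other 9 groups. Their Per1 mean of 8.04 lay under the 8.31 to 9.49 of the other 9 groups. A trait of these controls and an effect of chicory therefore both stay open.

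The acute phase list was higher under G35. Averaged over the sexes and at the preset correlation, the call does not rest on 1 mouse. It held without each of the 12 mice, at adjusted p from 1.09e-16 to 3.70e-07. In G35 females alone it ended without female G35 replicate 3 (adjusted p = 0.419). With slide in the model, also at the preset correlation, the adjusted p was 6.38e-08, so the averaged call does not rest on slide. Position on the slide was not tested. Infiltration by T and NK cells or neutrophils could not be decided: their markers averaged -0.13 ± 0.23 and -0.00 ± 0.08 log2. The members move together, and with the correlation estimated the adjusted p was 0.249. A response to G35 and an infection or injury that struck some mice of the G35 groups both stay open, as 2 of 3 female G35 mice and 3 of 3 male G35 mice lay above their controls' mean. Saa1 reached 15.04 in male control 2, given water, against a highest value of 15.36 in male and 15.66 in female G35. Such a level therefore also occurred without chicory.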

How the results depend on the processing

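Which alternatives were planned before the data were examined and which were added is given with the methods; all values under 75th percentile scaling, cyclic loess, the patch, no background correction, median centring of lists and the counts with slide in the model were added after seeing the data. Where a count moved, the cause was not tested unless said.

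Quantile normalization without background correction left 29 of 29 counts within 1.5 times, but it hardly changes the values (no G35 fold change averaged over the sexes by more than 0.0176 log2) and so tests little. Leaving out the dimmest genes left 24 of 25, masking the patch 18 of 20, every probe 14 of 16 and cyclic loess 22 of 29. With slide as a fixed block the gene counts were 3 (G12), 41 (G35) and 4 (inulin) averaged over the sexes, 32 (G35 males), 400 (G12 females), 77 (G35 females), 63 and 0 (sex difference of G12 and G35), 8 (G35 against G12), 5 (G35 against inulin) and 1139 (sex), and list counts were 2 (G12), 3 (G35) and 1 (G35 females). Slide as a random block gave 1 (G12), 33 (G35), 42 (G35 males), 1 (inulin males), 101 (G12 females), 4 (G35 females), 29 (sex difference of G12), 10 (G35 against G12), 1 (G35 against inulin) and 933 (sex). The replicate block gave 1 (G12), 3 (G35), 9 (G35 males), 1 (G12 females), 0 and 0 (sex difference of G12 and G35), 1 (sex difference of inulin, where the numbers pair nothing) and 2 lists in G12 females; with slide as well it gave 5 (G35), 0 (G35 males), 2 (G12 females) and 2 (G35 females).

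Fitting only the groups compared, which leaves fewer arrays for the spread, gave 0 genes for G35, G35 males, G12 females and the sex differences of G12 and G35, 248 for sex and 1278 for control 2 against control 1. Median centring gave 3 (G35), 2 (G12 females), 1 and 0 (sex difference of G12 and G35), with slide 17 (G35 males), 230 (G12 females) and 8 (G35 females), and 11 lists for inulin, 1 in G12 females and 5 in inulin females. Scaling by the 75th percentile gave 3 (G35), 1 (G12 females), 1 and 0 (sex difference of G12 and G35), 322 (sex), 1274 (control 2 against control 1), and 9 lists for inulin, 1 in G12 females and 4 in inulin females; it moved the median of all genes by 0.12 for inulin, 0.11 in inulin males, 0.15 in inulin females, -0.10 in G35 females and -0.17 for G35 against inulin. Cyclic loess gave 1 (G12), 4 (G35 males), 1 (sex difference of G35), with slide 25 (G35) and 12 (G35 females), and 1 list in inulin males and 1 in G12 females. Trend and robust gave 10 (G12 females), 2 (G35 females), 5 (sex difference of G12) and, with slide, 37 (G35 females). Every probe gave 4 (sex difference of G35) and 3741 (control 2 against control 1), where more probes than genes are tested. Masking the patch gave 0 (sex difference of G12) and, with slide, 167 (G12 females); leaving out its genes gave 1 list in G12 females. Leaving out dim genes gave 4 lists for G12. With the correlation estimated, list counts were 0 for G12, G35, inulin, inulin males, G35 females and inulin females and 1 each for G12 males and G35 males.

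Leaving out each array in turn gave gene counts of 0 to 0 (G12), 1 to 14 (G35), 0 to 9 (inulin), 0 to 0 (G12 males), 1 to 8 (G35 males), 0 to 15 (inulin males), 0 to 33 (G12 females), 0 to 5 (G35 females), 0 to 0 (inulin females), 0 to 52, 0 to 3 and 0 to 10 (sex difference of G12, G35 and inulin), 0 to 9 (G35 against G12), 0 to 2 (G35 against inulin), 344 to 635 (sex) and 1446 to 2451 (control 2 against control 1). With slide it gave 3 to 465 (G35), 2 to 23 (G35 males), 82 to 579 (G12 females) and 2 to 402 (G35 females). List counts were 1 to 10 (G12), 5 to 11 (G35), 3 to 9 (inulin), 7 to 13 (G12 males), 7 to 14 (G35 males), 0 to 9 (inulin males), 0 to 2 (G12 females), 2 to 4 (G35 females) and 1 to 6 (inulin females).

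Leaving out dim genes moved 1 of 25 counts; the largest shares moved with slide and replicate number together (4 of 4), the estimated correlation (8 of 9), slide as a random block (10 of 15) and slide as a fixed block (14 of 24). Median centring moved 10 of 29, only the groups compared 7 of 16, and the replicate block 8 of 23. The planned quantile normalization has no separate value because it became the normalization of every value.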

Other observations

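The counts over other splits were planned before the data were examined; all other values in this part were looked at after the results were seen.

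Genes of the exocrine pancreas varied between livers in the chicory experiment. Ctrb1, chymotrypsinogen, stood at 3.69 ± 1.29 log2 under G12 and Amy2a5, pancreatic amylase, at 1.88 ± 0.57, with unadjusted p of 0.00874 and 0.00289 and adjusted p of 0.887 and 0.846. Ctrb1 ran from 11.41 to 15.68 in the 3 male G12 mice and from 6.85 to 7.20 in male control 1, but also reached 11.46 in female control 1, 14.43 in female G12 and 14.92 in female G35. In the inulin experiment it stayed between 6.46 and 7.44. Amy2a5 ran from 9.84 to 13.49 in male G12 against 8.76 to 8.87 in male control 1. Both genes form the measured part of a list of pancreas markers too small to test, and no source was tested.

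At the preset correlation chaperones were higher under all 3 gavages, by 0.18 (G12), 0.20 (G35) and 0.26 (inulin) on average over the heat shock list. None of the 3 calls held with an estimated correlation (adjusted p = 0.590, 0.251 and 0.0653), and G12 and G35 share their control 1 mice, so they are not separate observations. Hsph1 stood at 0.42 ± 0.16, 0.46 ± 0.16 and 0.47 ± 0.16. With slide in the model the adjusted p was 0.118, 0.118 and 1.64e-06. Erythroid markers averaged -0.23 under G12 and -0.33 under inulin (-0.05 in inulin males and -0.60 in inulin females). Neither erythroid call held with an estimated correlation, and the G12 call ended without 8 of the 12 arrays. The lists of hepatocyte, endothelial, T and NK cell and neutrophil markers passed in none of the averaged comparisons. Eif2s3x, an X-linked gene chosen after its values were seen, is lower in females than in males here, with group means of 6.56 to 6.74 against 7.96 to 8.66. This is opposite to the usual direction of a gene that escapes X inactivation, and the target of its probe was not checked, so the value says little about sex labels.

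G12 and G35 fold changes correlated across genes at 0.523 (Spearman 0.578), where genes are not independent replicates. Both use the same control 1 mice, and simulated data with no effect gave 0.501. With the controls split between the decoctions the correlation had a median of -0.050 over 18 arrangements (-0.211 to 0.386). The parts of the controls were not balanced for slide, so slide offsets of opposite sign can lower this value. It cannot decide whether the decoctions share a response. G35 and inulin, with separate controls, correlated at 0.083, and G12 and inulin at 0.155.

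Counts over other splits of the same arrays set the results against chance. Each number of splits that gave as many includes the real split itself. For G35, averaged over the sexes, 2 of 100 splits gave as many genes as the real 5, and the highest other gave 27; that split puts slides 4 and 6 mostly against slide 1, and among the 19 splits that part as many replicate pairs 1 was as large, with 2 as the highest other. With slide in the model 2 of 100 gave as many as 41 (highest other 42), and among the 19 the highest other gave 0 genes. For lists, 11 of 100 gave as many as 8 under G35 (highest other 11), 9 of 100 as many as 7 under G12 (10) and 66 of 100 as many as 4 under inulin (15), so chance is not excluded for these. Single genes gave 0 for G12 and for inulin, which all 100 splits reach, and the highest other splits gave 63 and 223, which points to a structure of the samples that follows slides; with slide in the model the real counts were 3 and 4. Among the 17 splits for G12 that part as many replicate pairs the highest other was 2. For the sex differences, 3 of 100 gave as many as 2 under G12 (highest other 15), 4 of 100 as many as 2 under G35 (158, far above the real count, again a structure of the samples) and 100 of 100 as many as 0 under inulin (2); with as many replicate pairs parted the highest other was 1 for G12 (19 splits) and 1 for G35 (13 splits). For G35 against G12 and against inulin, with 0 genes, all 100 reach it (highest other 8 and 2). Sex and experiment stand apart: 1 of 100 reached 486 (highest other 107) and 1 of 100 reached 2058 (373).

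Within 1 sex there are 10 splits, the real one included, too few for a share under 0.05. For genes in males the real count and the highest other were 0 and 0 under G12 (10 of 10 splits as large), 1 and 3 under G35 (2 of 10), 32 and 4 under G35 with slide (1 of 10), and 0 and 5 under inulin (10 of 10). For lists in males they were 8 and 10 under G12 (4 of 10), 13 and 11 under G35 (1 of 10) and 5 and 17 under inulin (5 of 10). For genes in females they were 5 and 0 under G12 (1 of 10), 400 and 265 under G12 with slide (1 of 9 splits that could be fitted), 0 and 0 under G35 (10 of 10), 77 and 1 under G35 with slide (1 of 10), and 0 and 0 under inulin (10 of 10). For lists in females they were 0 and 4 under G12 (10 of 10), 4 and 9 under G35 (3 of 10) and 2 and 10 under inulin (9 of 10). The split of G12 females with 265 genes was fitted with the low-signal block included and sets slides 4, 6 and 6 against 1, 2 and 4, which follows slides in part, and the highest among the other splits with as many replicate pairs parted was 1.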
